A study of Heliconius melpomene malleti and Heliconius melpomene plesseni with 96 samples.

How the data were processed

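RNA from pupal wings and eyes of 2 races of Heliconius melpomene was labelled with Cy3 and hybridised to custom 12-array slides of 60-base probes, per the labels' protocols and the series' design text, with 1 sample per array and 96 arrays in 32 groups of 3 independent replicates. The group of every sample was taken from its labels for race, tissue and stage, and the replicate number from its title, in which each number occurs once. No paired analysis was therefore open. The numbers do not show whether tissues on different arrays came from the same individuals, which is not given in the sources used here. All arrays were treated as independent, so the tests take no account of shared individuals. The slide and the detector gain, at which 60 and 36 arrays were scanned, were read from the names of the array files; each slide had 1 gain and held 6 arrays of each race.

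The authors deposited 1 intensity per feature and array on a linear scale, summarised from the probes by RMA per the submitters' processing notes, which give no version. The background correction and other RMA settings are not given in the sources used here. The whole-series value table held equal values, with 0 differences, so it served as no separate alternative. Deposited standard errors, which are undefined for features of 1 probe, were not used. Most predicted genes, 11581 of 12778, were measured by 9 probes, 672 by 2 to 8 and 525 by 1; the AC, BD and YB walks had 16, 22 and 13 transcribed features of 3 probes each. The tiling probes of the walks were deposited as 1 summary per walk, over 6510, 10648 and 9938 probes, and were tested with the other features without being described.

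Median intensities between 22.98 and 376 showed that the arrays had not been brought to a common scale. The log2 of each intensity was therefore taken and the 96 arrays were quantile-normalized with limma version 3.58.1 in R version 4.3.3. The test had been fixed before the data were examined on the assumption that deposited values were already comparable, with quantile normalization as the alternative; the pair was exchanged before any comparison was computed, and the deposited log2 scale is now the alternative. A linear model with 32 group means was fitted to all arrays, leaving 64 residual degrees of freedom, and contrasts were tested with limma's moderated statistics (eBayes). The Benjamini-Hochberg adjustment was made over all 12832 features within each contrast, with a threshold of 0.05, and calls of at least 2-fold were counted separately. Contrasts averaged over days, races or wing sections with equal weights; race is plesseni minus malleti. The change of the race difference between days, the neighbour test and the tests of differences between wing and eye steps were added after the data were seen.

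The procedure was tested on simulated data of 12832 features, of which 100 were changed 2-fold and 100 were changed 4-fold. For race in the hindwing, 48% of 2-fold and 97% of 4-fold changes were recovered; for race in the hindwing on day 3 the shares were 7% and 49%. For distal against proximal forewing they were 71% and 99%, and 5.84%, 3.45% and 7.1% of the calls in these 3 simulations were unchanged features. These shares hold for the simulated data. With redrawn race labels, the real hindwing arrays gave up to 92 called features, although the median was 0. For distal against proximal forewing, all redrawn splits stayed below the real count of 67. The error and recovery shares may therefore not carry over to the real arrays. The number of arrays limits the precision of all values. Labels describe replicates as independent without further detail.

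Features were matched to the gene table supplied for this species (assembly ASM5695672v1), and 0 of the 12832 identifiers were found in it. The gene lists and named genes fixed before the data were examined could therefore not be looked up, and their tests were not run. Under the rule fixed for that case, at most 2 features that rose and 2 that fell with the largest changes among those called are named per comparison. The longest runs of neighbours, the single feature that passed for race by forewing section, its most similar feature and the examples of the walks were chosen after their values were seen.

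For the neighbour test, features of 1 scaffold that follow each other without overlap formed pairs, and the directions of calls of at least 2-fold were shuffled over features 100000 times with numpy version 2.4.6. Walk features were set against predicted genes with Fisher's exact test, adjusted over the 15 comparisons for all walks together. For each comparison, labels were redrawn within the remaining factors for 100 splits, the real one included.

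Alternatives fixed before the data were examined were the deposited log2 scale, centring on array medians, slide as a block, the arrays of each gain alone, leaving out the 25% of features with the lowest mean, eBayes with trend and robust options, array weights, only the groups of a contrast in the fit, and each array left out in turn. Limma's default estimate of array weights did not reach its tolerance, so its gene-by-gene method was used, a choice made after the data were seen, as were the fits without replicates 67 and 69, without the 10 arrays of median log2 intensity below 5.5, and without these 12. With 12 left out, 10 groups kept 2 arrays and 1 group kept 1, whose spread is assumed to equal that of the other groups. Each slide held at most 2 arrays of a group, too few for a fit within a slide.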

Results

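Expression was measured in pupal wings and eyes of Heliconius melpomene malleti and Heliconius melpomene plesseni, races of one butterfly species that differ in wing colour pattern. Each race was sampled on days 1, 3, 5 and 7 in 4 tissues, namely the proximal forewing, the distal forewing, the hindwing and the eye. The 32 combinations of race, tissue and day were each measured in 3 independent replicates, giving 96 one-colour Cy3 arrays on 8 slides of 12 arrays. Samples are named here by their group and a replicate number that runs from 1 to 96 over the whole series. Each array gave 1 intensity for each of 12832 features. Of these, 12778 were predicted genes named by scaffold and position, and 51 were transcribed features of 3 sequenced walks called AC, BD and YB, names shared with the Ac, B/D and Yb colour pattern loci of this species. No feature carried a gene name, so features are given by scaffold, start and end, on a genome build not given in the sources used here.

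The median intensity per array ranged from 22.98 to 376, with a median of 125, so arrays differed widely in brightness before normalization. Pairs of arrays of one group correlated with a median Pearson r of 0.946 across features, against 0.861 for arrays of different groups. The first principal component, holding 19% of the variance, separated wings of days 1 and 3 from wings of days 5 and 7, and the second, holding 17%, separated eyes from wings by label, except replicates 67 and 69 and replicate 55. The last, a dim array labelled malleti distal forewing day 3, lay among the eyes at -85.82 on the second component and on the side of the later wings, at 31.76, on the first. In the array labelled malleti proximal forewing day 7, replicate 69, the Spearman correlation was 0.983 with the eyes of day 7 and 0.870 with the proximal forewings of day 7. In the array labelled malleti eye day 7, replicate 67, it was 0.873 with the eyes of day 7 and 0.974 with the distal forewings of that day. Another 10 arrays had a median log2 intensity below 5.5, namely replicates 5, 8, 16, 21, 32, 34, 42, 55, 60 and 73. Replicates 8 and 60 were 2 of the 3 plesseni eye arrays of day 3. These 12 arrays are called the doubted arrays. Unless stated otherwise, counts come from the 96 arrays with their labels as given. Counts without the 12, a setting chosen after the data were seen, stand beside some of them.

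**Figure D1:**
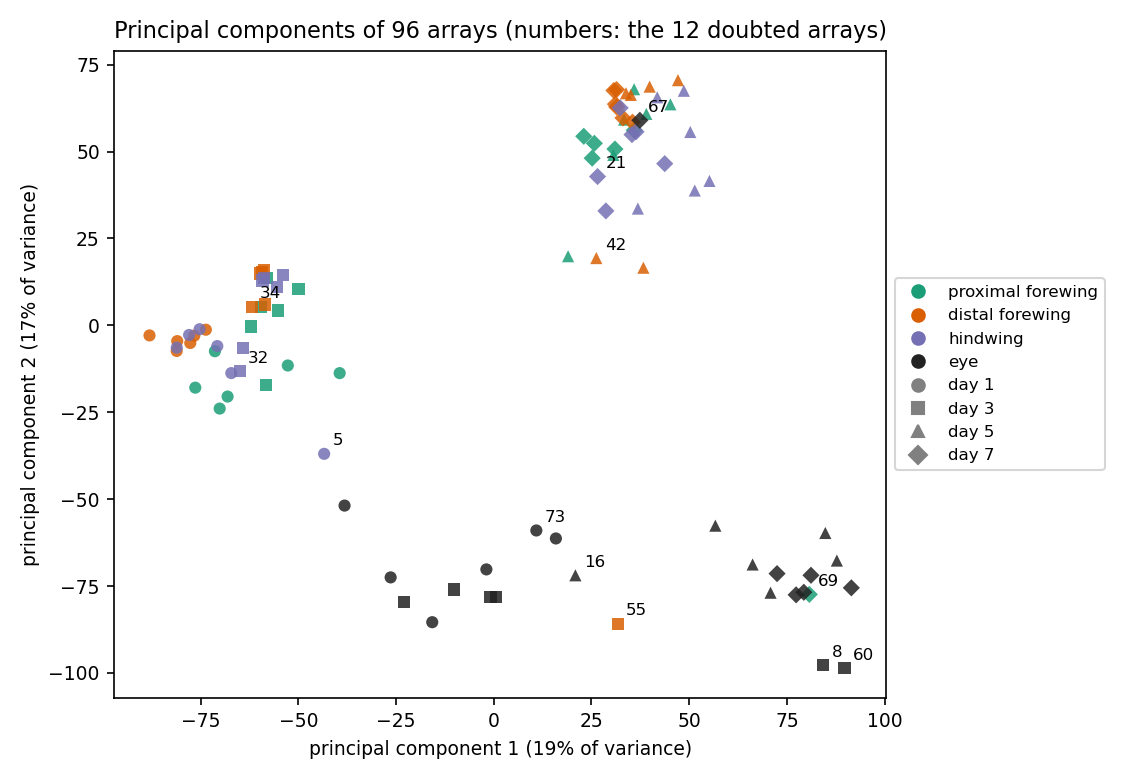
Position of each of the 96 arrays on principal component 1 (horizontal, 19% of variance) and principal component 2 (vertical, 17% of variance) of the quantile-normalized log2 values; colour gives the tissue, symbol the day, and numbers mark the 12 doubted arrays. Replicate 67, labelled eye, lies among wings of days 5 and 7, and replicate 69, labelled proximal forewing, lies among eyes of those days. Replicate 55, labelled distal forewing of day 3, lies on the side of the eyes.

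**Figure D2:**
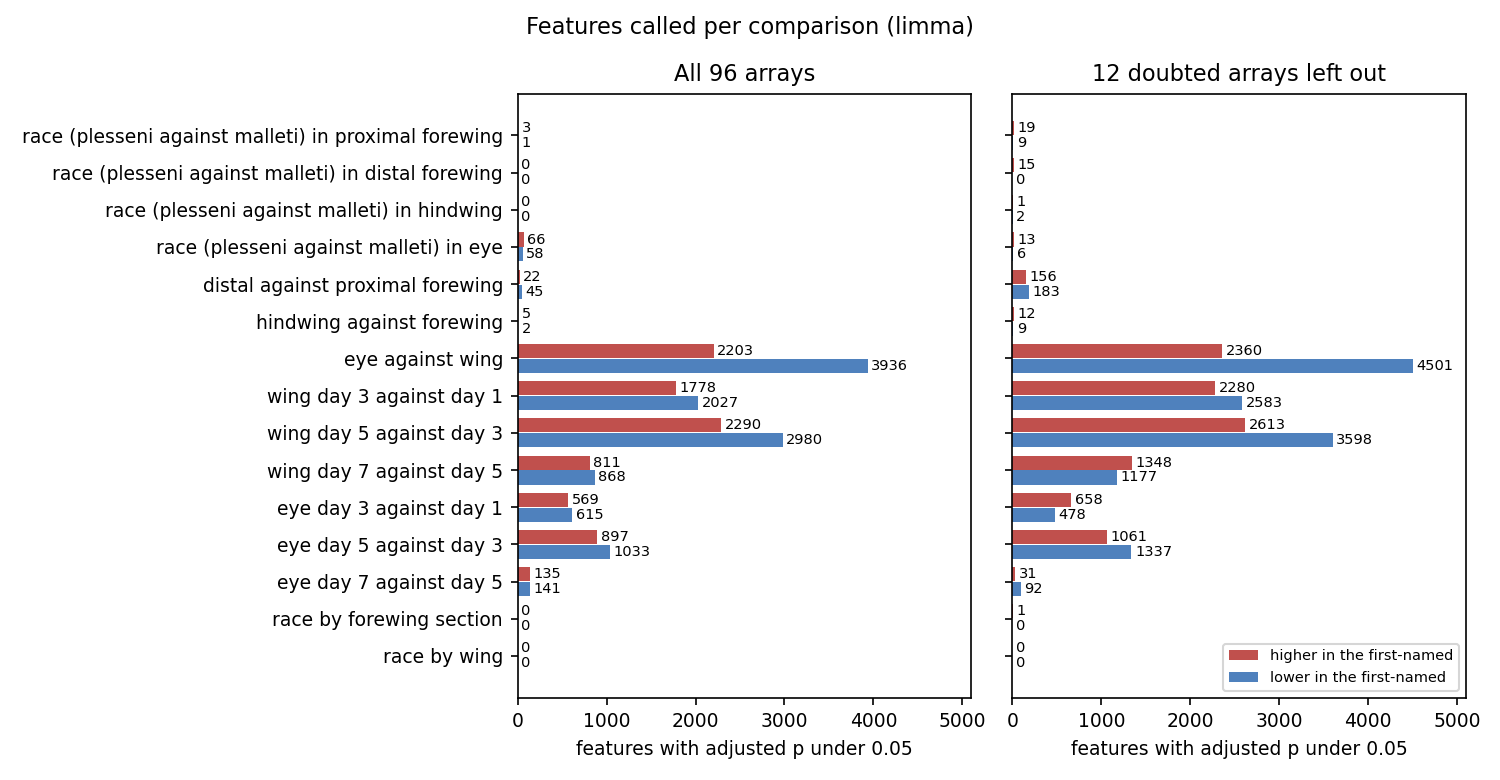
Number of features (horizontal axis) with an adjusted p under 0.05 in limma for each comparison (vertical axis), split into features higher (red) and lower (blue) in the group named first, with all 96 arrays on the left and without the 12 doubted arrays on the right. The eye and the wing differed at 2203 features higher and 3936 lower with all arrays, while race averaged over days numbered at most 124 within a tissue with all arrays.

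The eye differed from the wing at 6139 of the 12832 features, 2203 higher and 3936 lower in the eye, and 1785 of them differed at least 2-fold. The feature at HE671174 1057577 to 1066913 was 126-fold higher in the eye, with a log2 value of 12.31 ± 2.44 (SD, n = 24) against 5.33 ± 1.56 (SD, n = 72) in the wing (limma, adjusted p = 9.91e-25). HE671990 58824 to 62427 was 96.8-fold higher in the eye (log2 change 6.60 ± 0.34, SE; adjusted p = 1.15e-26). In the opposite direction, HE670797 113155 to 117101 was 15.96-fold lower (log2 change -4.00 ± 0.23, SE; adjusted p = 6.41e-25) and HE671890 39882 to 42605 was 8.25-fold lower in the eye (log2 change -3.04 ± 0.36, SE; adjusted p = 3.98e-11). A stretch of 7 neighbouring features on HE670910 from 215432 to 258521 was higher in the eye throughout, by a median log2 change of 2.63. The direction of small differences moved with the scaling: 2236 features were higher and 788 lower on the deposited values without quantile normalization, and 1624 were higher and 5921 lower after centring on array medians. The median change over all features was -0.161 on the quantile-normalized scale, 0.034 on the deposited scale and -0.401 after centring; the named features kept their sign on each.

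Within the forewing, 67 features differed between the distal and the proximal section, 22 higher and 45 lower distally. HE671568 80846 to 96316 was 7.54-fold lower in the distal section, with a log2 value of 5.18 ± 0.87 (SD, n = 24) against 8.10 ± 1.62 (SD, n = 24) proximally (limma, adjusted p = 1.75e-13). HE670742 105967 to 137673 was 5.03-fold lower distally (log2 change -2.33 ± 0.19, SE; adjusted p = 4.35e-15). The largest rise among the called features was that of HE669530 141744 to 174551, which was 2.44-fold higher in the distal section (log2 change 1.29 ± 0.15, SE; adjusted p = 5.04e-09), followed by HE671453 24081 to 25111 at 2.36-fold (adjusted p = 0.0281). A total of 339 features differed without the doubted arrays, 156 higher and 183 lower. The split was 4 higher and 24 lower on the deposited scale, 14 higher and 53 lower after centring on array medians, and leaving out replicate 55 alone gave 109 features.

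The hindwing differed from the forewing at 7 features, all by at least 2-fold, 5 higher and 2 lower in the hindwing. HE667779 82647 to 83106 was 31.6-fold higher in the hindwing, with a log2 value of 11.86 ± 1.32 (SD, n = 24) against 6.88 ± 1.68 (SD, n = 48) in the forewing (limma, adjusted p = 5.1e-22). HE667776 139980 to 169655 was 4.79-fold higher (log2 change 2.26 ± 0.15, SE; adjusted p = 1.25e-19). Lower in the hindwing were HE671488 990436 to 994927, by 2.26-fold (adjusted p = 5.80e-04), and the AC walk feature at 365755 to 380944, by 2.15-fold (log2 change -1.10 ± 0.18, SE; adjusted p = 2.44e-04). The predicted gene with equal coordinates, HE668478:365755-380944, gave a log2 change of -0.85 ± 0.20 (SE; adjusted p = 0.0638). With the doubted arrays left out, 21 features differed, 12 higher and 9 lower. The deposited scale gave 5 higher and 0 lower, centring on array medians gave 5 higher and 1 lower, and the leave-one-out counts ran from 6 to 15, the highest without replicate 82.

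Across the wing sections and both races, the step from day 1 to day 3 changed 3805 features, 1778 upward and 2027 downward. Arrays of the wing sections were counted as independent, although sections may come from the same individuals. HE671547 73513 to 80980 rose 365-fold, from a log2 value of 4.20 ± 0.55 to 12.71 ± 1.67 (SD, n = 18 each; limma, adjusted p = 2.33e-30), and HE670537 48899 to 54230 rose 271-fold (log2 change 8.08 ± 0.51, SE; adjusted p = 3.22e-22). HE670342 30 to 224, measured by 3 probes, fell by 7.85 on the log2 scale (adjusted p = 6.45e-26), and HE670515 13623 to 20570 fell by 7.33 (adjusted p = 1.67e-24). From day 3 to day 5, 5270 features changed, 2290 upward and 2980 downward. The pair that had risen by day 3 fell again, HE670537 48899 to 54230 by 7.42 and HE671547 73513 to 80980 by 7.14 on the log2 scale (adjusted p = 1.81e-20 and 2.61e-26). HE671226 164893 to 167361 and HE669301 108681 to 113035 rose 253-fold and 232-fold at this step (adjusted p = 4.55e-24 and 3.19e-33).

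From day 5 to day 7 the wing changed at 1679 features, 811 upward and 868 downward. HE669301 108681 to 113035 fell by 6.61 on the log2 scale, from 11.40 ± 0.86 on day 5 to 4.79 ± 0.70 on day 7 (SD, n = 18 each; limma, adjusted p = 6.76e-29). HE671115 223830 to 225883 fell by 7.22 (adjusted p = 2.68e-19). HE669253 13633 to 14161 rose 39.3-fold (adjusted p = 2.28e-10) and HE670988 2353 to 2955 rose 32.7-fold (adjusted p = 1.39e-08), measured by 3 and 2 probes. The 3 steps counted 4863, 6211 and 2525 features without the doubted arrays. On the deposited scale the splits were 802 upward and 1443 downward at the first step, 1583 and 1788 at the second, and 374 and 278 at the third, where the majority turned.

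Neighbouring features often moved together, in the wing and in the eye. Among 9535 pairs of adjacent features that did not overlap, 284 pairs changed at least 2-fold in the same direction from day 1 to day 3, against a mean of 108 when the calls were shuffled over the features (one-sided permutation test, 100000 shuffles, p = 1e-05, the smallest they can give). For the step from day 3 to day 5 the count was 462 pairs against 218, and from day 5 to day 7 it was 83 against 18.7, each with the same p. Between distal and proximal forewing it was 5 pairs against 0.061, again with the smallest p. In the eye the same permutation test gave for the steps 81 pairs against 30.9, 171 against 78.1 (each with the smallest p) and 9 against 1.97 (p = 0.0002), and eye against wing gave 251 against 100 (p = 1e-05). Race in the eye, with 1 pair against 0.149, did not pass (permutation test, p = 0.139). The longest run, singled out after the values were seen, was 12 features on HE671115 between 118988 and 291449, all higher on day 3 than on day 1 in the wing, by a median of 5.93 on the log2 scale. One further feature overlapped the last of these. Of the 13 features, 10 also rose in the eye at that step, and from day 3 to day 5 the number that fell was 9 in the wing and 9 in the eye. Not all of these features peaked on 1 day: within the stretch, the feature at 268900 to 269670 stood at 14.83 on day 3 and 8.30 on day 5 in the wing, whereas that at 207563 to 212194 stood at 6.79 on day 3 and 11.01 on day 5. Whether these neighbours share probe sequence was not analysed here.

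**Figure D3:**
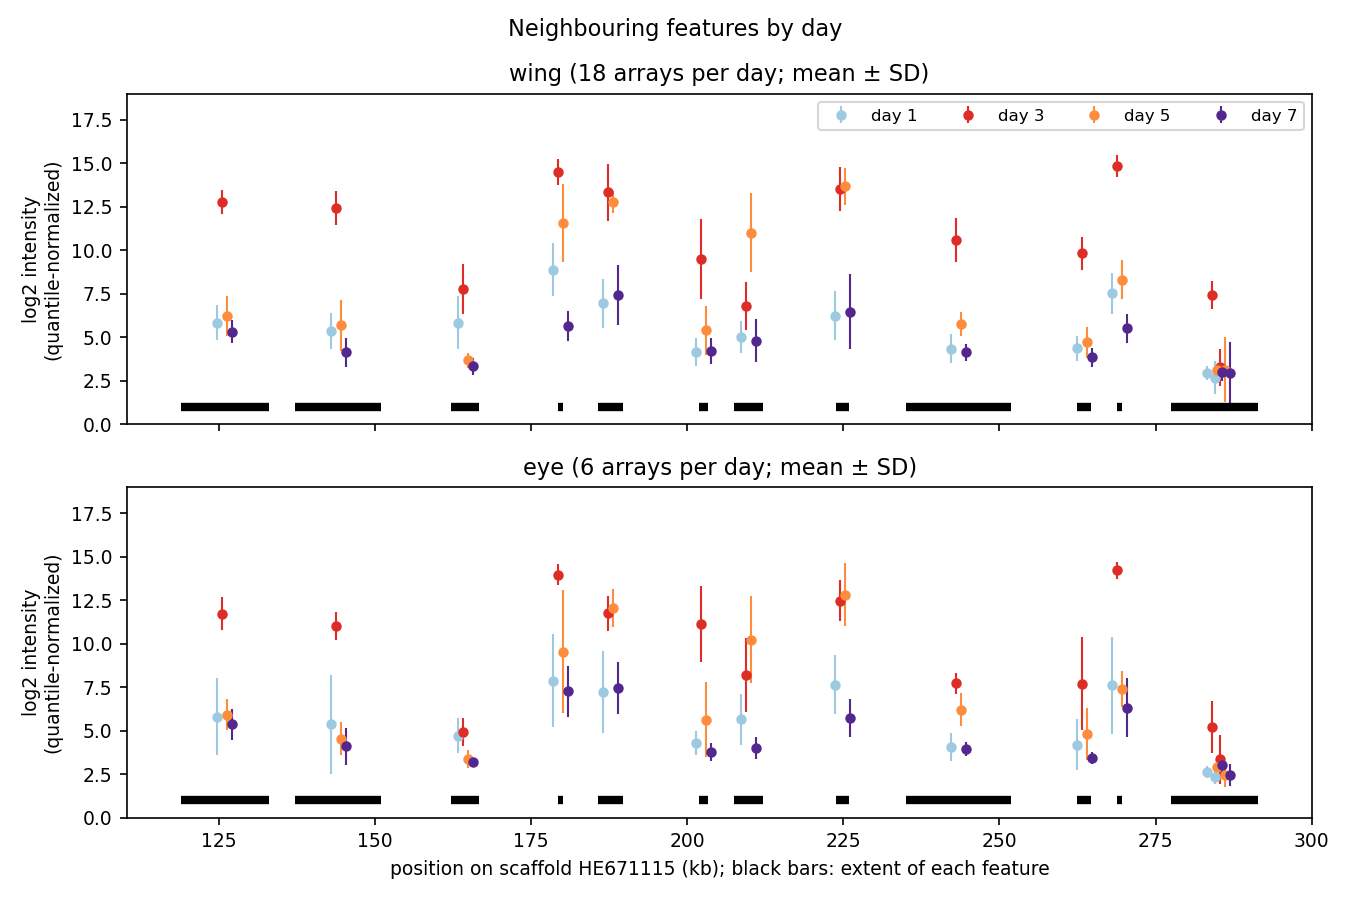
Mean log2 intensity (vertical axis, ± SD over arrays) of the 13 features between 118988 and 291449 on scaffold HE671115 (horizontal axis, position in kb), for the wing above (18 arrays per day) and the eye below (6 arrays per day); colours give the day and black bars the extent of each feature. Most features stand highest on day 3 in both tissues, and the feature at 207563 to 212194 stands highest on day 5.

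Other runs of at least 6 features were chosen by the same after-the-fact rule. On HE669253, 6 of 6 features from 4228 to 20427 were higher in the eye than in the wing, by a median log2 change of 1.42, and 5 of them rose in the wing from day 5 to day 7. On HE671524, 6 of 6 features from 7760 to 67002 rose in the wing from day 1 to day 3, by a median log2 change of 2.53, and 3 of them fell at each later step. On HE667780, 5 of 7 features from 619896 to 867595 rose by day 3 and 6 fell by day 5, with median log2 changes of 0.64 and -1.59. On HE671280, 7 features from 748238 to 788469 fell from day 1 to day 3 with a median log2 change of -2.65, and 0 of them changed at that step in the eye. On HE671875, 7 of 9 features from 43665 to 223808 rose by day 3, with a median log2 change of 0.99, and all 9 fell from day 3 to day 5, with a median of -1.61, against 0 called in the eye at either step. On HE672080, 7 features from 130553 to 260010 rose from day 3 to day 5 by a median log2 change of 3.54, and 2 of them rose in the eye. The stretch on HE670910 that was higher in the eye rose from day 3 to day 5 in both, at 7 of 7 features in the wing and 6 of 7 in the eye. These call counts do not test whether wing and eye differed at a given feature.

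In the eye, 1184 features were called from day 1 to day 3, 1930 from day 3 to day 5 and 276 from day 5 to day 7. These tests used a spread estimated over all 32 groups, wings included. HE671115 201882 to 203281 rose 115-fold by day 3, from a log2 value of 4.29 ± 0.68 to 11.14 ± 2.20 (SD, n = 6 each; limma, adjusted p = 1.57e-08), and HE670537 48899 to 54230, which had risen in the wing, rose 113-fold (adjusted p = 3.74e-08). HE670515 13623 to 20570, which had fallen in the wing, fell by 5.44 on the log2 scale in the eye (adjusted p = 7.62e-08). From day 3 to day 5, HE671536 14945 to 20009 fell by 6.93 (adjusted p = 2.64e-13) and HE671609 259171 to 263965 rose 52.1-fold (adjusted p = 6.64e-05). From day 5 to day 7, HE671115 223830 to 225883 fell by 7.08, next to 7.22 in the wing, and the BD walk feature at 582915 to 585908 rose 5.55-fold (adjusted p = 4.24e-08 and 0.00769). Calls of wing and eye, which come from separate arrays, were shared in direction at 258 rising and 303 falling features from day 1 to day 3, where independent lists would share 78.8 and 97.1. From day 3 to day 5, 436 rose and 483 fell in both, against 160 and 240. Whether wing and eye samples share individuals is not given in the sources used here.

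In the eye, the splits of rising and falling features were 569 and 615, 897 and 1033, and 135 and 141 for the 3 steps; on the deposited scale they were 64 and 214, 1342 and 48, and 1 and 30, and after centring on array medians they were 204 and 98, 391 and 329, and 25 and 68. They were 1136, 2398 and 123 in number without the doubted arrays. With only the groups of each comparison in the fit, and so no wing arrays, they were 211, 229 and 16. Leaving out single arrays moved them between 642 and 3260, between 1141 and 3746, and between 69 and 1892, with the extremes at replicates 51 and 82, 60 and 82, and 24 and 38. With redrawn day labels, 26, 10 and 1 of 100 splits, the real one included, gave at least as many features. Chance was therefore not excluded for the counts of the steps from day 1 to day 3 and from day 3 to day 5.

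Averaged over days, the races differed at few features within each tissue. In the proximal forewing 4 features differed, 3 higher and 1 lower in plesseni, and 508 had an unadjusted p under 0.05. HE671135 357775 to 363080 was 7.57-fold higher in plesseni, with a log2 value of 9.87 ± 0.71 against 6.95 ± 2.60 (SD, n = 12 each; limma, adjusted p = 0.03), and without the doubted arrays it was 8.78-fold higher there (adjusted p = 5.11e-04) and 6.73-fold higher in the distal forewing (adjusted p = 0.0215). HE670617 54328 to 55967 was 3.25-fold higher (limma, adjusted p = 0.00741) and HE671073 131213 to 142905 was 2.29-fold lower in plesseni (limma, adjusted p = 0.0364). Over the alternative settings, including each array left out in turn, the call of HE671135 was kept in 20 and lost in 16. That of HE670617 was kept in 30 and lost in 5, and that of HE671073 was kept in 14 and lost in 22. In the distal forewing and the hindwing limma called 0 features, with 694 and 361 at an unadjusted p under 0.05. Leaving out the doubted arrays gave counts of 28 in the proximal forewing, 15 in the distal forewing and 3 in the hindwing. The proximal count fell to 0 on the deposited scale and ran from 1 without replicate 78 to 12 without replicate 76.

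In the eye 124 features differed between the races, 66 higher and 58 lower in plesseni. HE672064 425079 to 426535 was 5.90-fold lower in plesseni, at 4.85 ± 0.86 against 7.41 ± 1.56 (SD, n = 12 each; limma, adjusted p = 2.26e-04), and it was 3.77-fold lower without the doubted arrays (adjusted p = 0.0136). HE671271 320898 to 321828 was 10.8-fold higher (adjusted p = 0.04), and its adjusted p was 0.693 without the doubted arrays. The count was 19 without the doubted arrays, 27 with the slide in the model and 2 on the deposited scale, and it ran from 15 without replicate 7 to 2335 without replicate 82. With only the eye groups in the fit it was 1. With redrawn race labels, 16 of 100 splits, the real one included, gave at least as many features, so chance was not excluded. The number of features called by limma in all 4 tissues was 0. It could not be otherwise, because the distal forewing and the hindwing had 0 calls, so it does not bear on shared race differences.

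Taken day by day, 4250 features differed between the races in at least 1 tissue, and 4005 features were called in the eye of day 3, the group that holds replicates 8 and 60. Over other splits with redrawn race labels the median total was 387 and the highest 4320. Without the doubted arrays the total was 1011, against a median of 318 and a highest of 1012 over such splits. Another split thus passed the real total in each fit, so chance was not excluded. The total without the doubted arrays includes the eye of day 3, where plesseni keeps only replicate 82. The count of that eye alone is therefore not given. Without the doubted arrays the counts in each wing section were highest on day 1, followed by day 3. On days 1 and 3 they were 286 and 104 features in the proximal forewing, 77 and 23 in the distal forewing and 33 and 16 in the hindwing. The eye of day 1 gave 331. On days 5 and 7 each tissue gave 0 to 15. With all arrays the counts of days 1 and 3 were 69 and 30 in the proximal forewing, 18 and 3 in the distal forewing and 2 and 11 in the hindwing. The eye of day 1 gave 197. In the hindwing, days 5 and 7 gave 2 and 3 with all arrays, so day 1 did not stand out there. The test of whether the race difference changed between days found 16 features in the proximal forewing, 0 in the distal forewing (limma, 554 at an unadjusted p under 0.05), 2 in the hindwing and 2325 in the eye. It found 86, 16 and 15 in the wing sections without the doubted arrays. The count for the eye is left out, because its day 3 then keeps 1 plesseni array.

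With all arrays, limma found 0 features at which the race difference itself differed between the distal and the proximal forewing, with 212 at an unadjusted p under 0.05, and 0 at which it differed between the hindwing and the forewing, with 81. Without the doubted arrays 1 feature passed for the forewing sections, the BD walk feature at 518010 to 518813, singled out after its values were seen. Its race difference in the distal section exceeded that in the proximal section by 2.72 ± 0.53 on the log2 scale (SE; adjusted p = 0.0428), against 2.26 ± 0.78 (adjusted p = 0.999) with all arrays. In the proximal forewing it was 3.50-fold lower in plesseni (log2 change -1.81 ± 0.36, SE; adjusted p = 0.011), and in the distal forewing the difference was 0.91 ± 0.38 (adjusted p = 0.682). On day 7 its log2 value in the hindwing was 9.26 ± 0.08 in malleti (SD, n = 2) and 5.69 ± 0.88 in plesseni (SD, n = 3), a difference of -3.57 whose adjusted p in limma was 0.0604. The feature whose values across the 84 remaining arrays were most similar was HE670865 438423 to 439107 (r = 0.942, next highest 0.544). It was deposited as a separate probe set, and whether the sets share probe or target sequence was not analysed here. This feature was 2.86-fold lower in plesseni in the proximal forewing (limma, adjusted p = 0.0134), with a difference between the sections of 2.08 ± 0.46 (SE, adjusted p = 0.191).

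**Figure D4:**
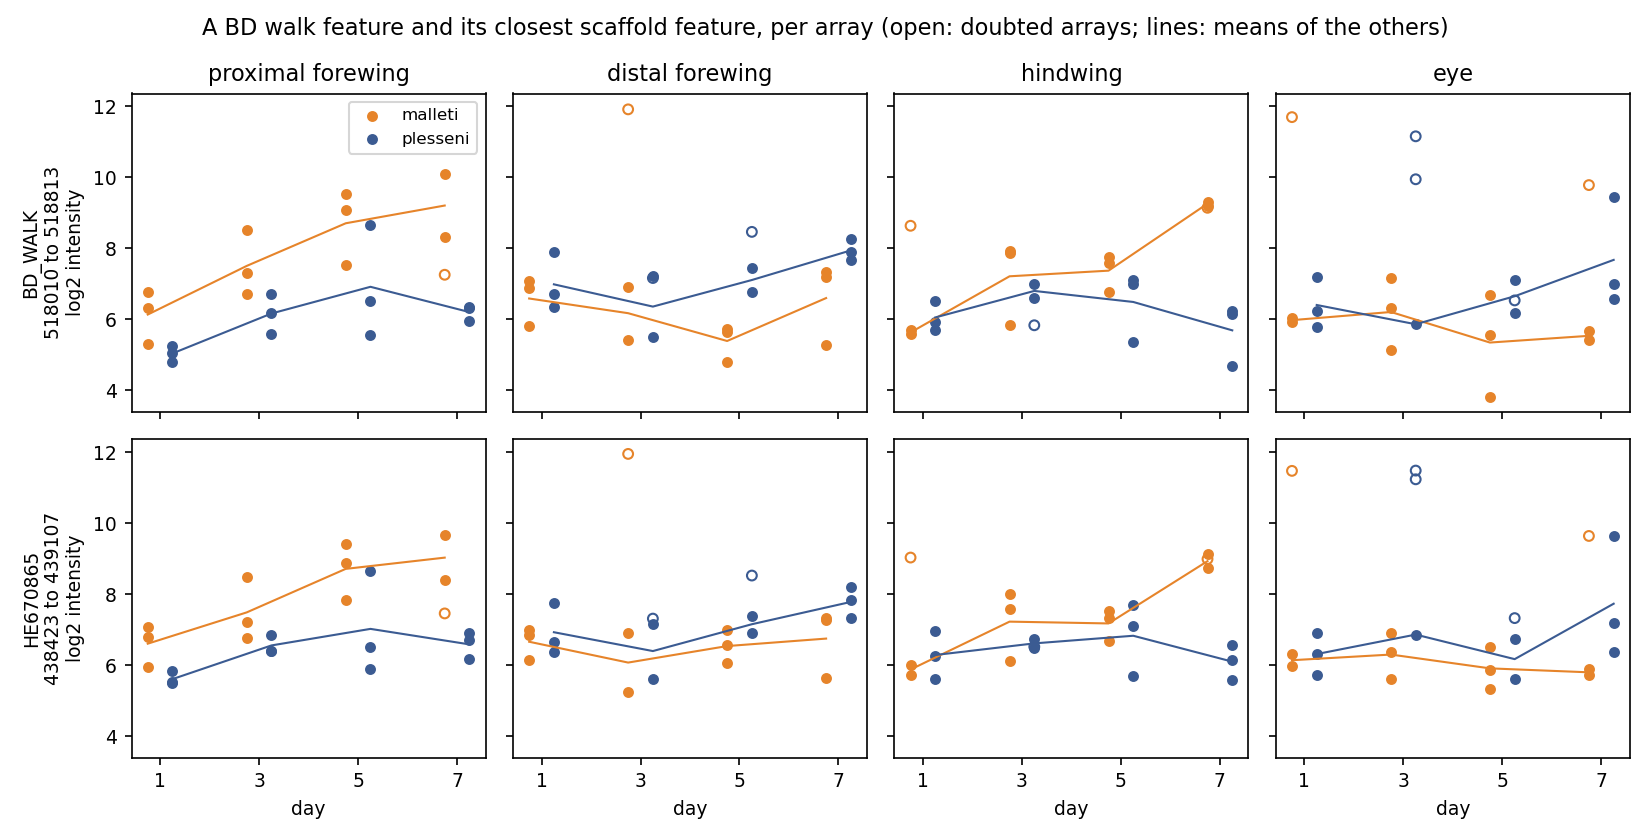
Log2 intensity (vertical axis, quantile-normalized) of the BD walk feature at 518010 to 518813 above and of HE670865 438423 to 439107 below on each array, by day (horizontal axis), tissue (panels) and race (colour); open symbols are doubted arrays and lines join the means of the others. On day 7 the 2 filled malleti hindwing points of the BD walk feature average 9.26 and the 3 plesseni points 5.69.

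The features of the 3 walks were described as groups, with some examples. For race averaged over days, limma called 0 of the 51 in each wing section and 3 in the eye with all arrays. Without the doubted arrays it called 1 in the proximal forewing and 0 in each other tissue. Between eye and wing, 20 of the 51 were called, 19 of them lower in the eye: 7 of 16 in the AC walk, 6 of 22 in the BD walk and 7 of 13 in the YB walk. The share of 39.2% was not distinguishable from the 47.9% among predicted genes (two-sided Fisher's exact test, adjusted p = 0.75). From day 1 to day 3 in the wing, 6 of 51 were called, 2 higher and 4 lower, a share of 11.8% against 29.7% of predicted genes (Fisher's exact test, adjusted p = 0.0506). The AC walk feature at 450400 to 483854 fell by 2.99 on the log2 scale at that step (limma, adjusted p = 3.28e-19). From day 3 to day 5 in the wing 19 of 51 were called, 16 of them lower. On day 5, without the doubted arrays, the BD walk feature at 270714 to 272686 was 9.8-fold higher in plesseni in the distal forewing and 8.08-fold in the hindwing (limma, adjusted p = 0.0348 and 0.0275, with all arrays 0.528 and 0.271). The AC walk feature at 450400 to 483854 was 3.77-fold lower in plesseni in the proximal forewing of day 3 (limma, adjusted p = 0.0412, with all arrays 0.128). All 16 AC features were also present as predicted genes with equal coordinates on HE668478 and other probe sets; the paired values correlated across the 96 arrays with a median r of 0.851, and r exceeded 0.5 for 15 of 16.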

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

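All tests in this part were chosen after the results were seen. The race difference changed between days at 16 features in the proximal forewing, 2 in the hindwing and 2325 in the eye, by a test of the difference itself. Without the doubted arrays the counts were 86 in the proximal forewing and 15 in the hindwing. The eye is left out there, because its day 3 keeps 1 plesseni array. The steps between days differed between wing and eye at 1103 features from day 1 to day 3, 1791 from day 3 to day 5 and 74 from day 5 to day 7. Of these, 573, 968 and 32 changed more upward in the wing than in the eye. Without the doubted arrays the counts were 1923, 1826 and 102.

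The 2325 features in the eye and the 4005 features called between races in the eye of day 3 were followed further. Replicates 8 and 60 correlated with each other at r = 0.883 across features, but with the remaining plesseni eye array of day 3, replicate 82, at a mean of 0.661. Dim replicate 55, of the other race and labelled distal forewing, correlated with them at a mean r of 0.811, against 0.638 with its own group and 0.652 with the malleti eyes of day 3. A wrong label of replicate 55, which lay among the eyes at -85.82 on the second principal component, stays open. Not every dim array left its group. Replicates 21 and 34, with median log2 intensities of 5.17 and 5.29 against 5.22 in replicate 55, correlated with their own groups at a mean r of 0.938 and 0.944. Replicates 8 and 60 were dimmer, at 4.74 and 4.52. Low signal of replicates 8 and 60 as a source of the calls therefore stays open. Replicate 82 moved with replicates 8 and 60 away from malleti with a slope of 0.0733. A race difference of equal size in all 3 arrays would give a slope near 1 without noise, and noise in the dim arrays lowers it. The mean r of replicate 82 with the malleti eyes of day 3 was 0.917, against 0.683 for replicates 8 and 60. As this is 1 array, a race difference cannot be told apart from a lack of one. Without replicates 8 and 60 the plesseni eye of day 3 keeps 1 array, so a race difference in the eye stays open.

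Replicates 67 and 69 lay with the other organ. On the axis between the organs on day 7, replicate 67 lay 0.942 of the way from eye to wing and replicate 69 lay 0.988 of the way from proximal forewing to eye, whereas the other 21 undoubted arrays lay between -0.0236 and 0.144 of the way. These values are consistent with an exchange of the samples or their labels and argue against mixtures of both organs. Their best Spearman correlations with a tissue on day 7 were 0.974 and 0.983, above the median of 0.964 for undoubted arrays and their own groups, which argues against poor hybridisation or RNA. No biological explanation was tested.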

How the results depend on the processing

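The fits with array weights of the gene-by-gene method and without replicates 67 and 69, without the 10 dim arrays or without all 12 were chosen after seeing the data; the others were fixed before the data were examined. Counts not given here lay within 1.5 times the main count, and the trend and robust options moved none beyond it. The cause of the changes was not tested, beyond fewer arrays or features in settings that leave some out. No paired analysis was possible because each replicate number occurs in 1 group. The source of values gave equal numbers and was not rerun, and gene lists had no members to test. On the deposited log2 values without quantile normalization, counts were 0 for race in the proximal forewing, 1 for race in the distal forewing, 2 for race in the eye, 28 for distal against proximal forewing, 3024 for eye against wing, 2245 for wing day 3 against day 1, 3371 for wing day 5 against day 3, 652 for wing day 7 against day 5, 278 for eye day 3 against day 1, 31 for eye day 7 against day 5 and 8163 for race on any single day. With deposited values centred on array medians, counts were 2 for race in the proximal forewing, 1 for race in the distal forewing, 1 for race in the eye, 302 for eye day 3 against day 1, 720 for eye day 5 against day 3 and 93 for eye day 7 against day 5. With the slide as a block, counts were 27 for race in the eye and 738 for eye day 7 against day 5. Within the 60 arrays scanned at the lower gain, counts were 0 for race in the proximal forewing, 2 for race in the distal forewing, 795 for race in the eye, 29 for distal against proximal forewing, 4 for hindwing against forewing, 2243 for wing day 3 against day 1, 834 for wing day 7 against day 5, 1179 for eye day 5 against day 3 and 28 for eye day 7 against day 5. Within the 36 arrays scanned at the higher gain, counts were 7 for race in the proximal forewing, 5 for race in the distal forewing, 0 for race in the eye, 0 for distal against proximal forewing, 1 for hindwing against forewing, 1948 for eye against wing, 1012 for wing day 3 against day 1, 853 for wing day 5 against day 3, 85 for wing day 7 against day 5, 33 for eye day 3 against day 1, 49 for eye day 5 against day 3, 8 for eye day 7 against day 5 and 2328 for race on any single day. Without the dimmest 25% of features, counts were 0 for race in the proximal forewing, 48 for race in the eye and 4 for hindwing against forewing. With array weights, counts were 111 for race in the proximal forewing, 47 for race in the distal forewing, 197 for race in the hindwing, 2324 for race in the eye, 936 for distal against proximal forewing, 334 for hindwing against forewing, 7453 for wing day 3 against day 1, 3134 for wing day 7 against day 5, 3898 for eye day 3 against day 1, 3443 for eye day 5 against day 3, 2 for race by wing, 10169 for race on any single day and 1 for race in all tissues. With only the groups of each comparison in the fit, counts were 18 for race in the proximal forewing, 1 for race in the distal forewing, 1 for race in the hindwing, 1 for race in the eye, 101 for distal against proximal forewing, 18 for hindwing against forewing, 211 for eye day 3 against day 1, 229 for eye day 5 against day 3, 16 for eye day 7 against day 5 and 1458 for race on any single day. Without replicates 67 and 69, counts were 45 for race in the eye, 15 for hindwing against forewing and 152 for eye day 7 against day 5. Without the 10 dim arrays, counts were 34 for race in the proximal forewing, 11 for race in the distal forewing, 2 for race in the hindwing, 11 for race in the eye, 340 for distal against proximal forewing, 13 for hindwing against forewing, 157 for eye day 7 against day 5 and 737 for race on any single day. Without the 12 doubted arrays, counts were 28 for race in the proximal forewing, 15 for race in the distal forewing, 3 for race in the hindwing, 19 for race in the eye, 339 for distal against proximal forewing, 21 for hindwing against forewing, 2525 for wing day 7 against day 5, 123 for eye day 7 against day 5, 1 for race by forewing section and 1011 for race on any single day. With 1 array left out in turn, counts ran from 1 to 12 for race in the proximal forewing, 0 to 1 for race in the distal forewing, 0 to 1 for race in the hindwing, 15 to 2335 for race in the eye, 50 to 109 for distal against proximal forewing, 6 to 15 for hindwing against forewing, 5779 to 6613 for eye against wing, 3613 to 4044 for wing day 3 against day 1, 5078 to 5550 for wing day 5 against day 3, 1513 to 1856 for wing day 7 against day 5, 642 to 3260 for eye day 3 against day 1, 1141 to 3746 for eye day 5 against day 3, 69 to 1892 for eye day 7 against day 5, 0 to 4 for race by forewing section, 0 to 0 for race by wing, 1962 to 5998 for race on any single day, 0 to 0 for race in all tissues. Those beyond 1.5 times the main count were as follows. Race in the proximal forewing: 2 without replicate 1, 2 without 2, 2 without 9, 7 without 17, 7 without 26, 2 without 62, 2 without 63, 2 without 70, 12 without 76, 2 without 77, 1 without 78, 7 without 82, 2 without 92, 2 without 95. Race in the eye: 74 without replicate 3, 78 without 4, 74 without 6, 15 without 7, 17 without 8, 76 without 12, 82 without 13, 40 without 15, 75 without 22, 36 without 23, 16 without 24, 38 without 29, 38 without 30, 49 without 37, 189 without 46, 75 without 48, 47 without 51, 80 without 53, 334 without 55, 65 without 59, 18 without 60, 23 without 67, 76 without 72, 264 without 73, 35 without 74, 79 without 75, 63 without 81, 2335 without 82, 79 without 83. Eye day 3 against day 1: 781 without replicate 7, 779 without 8, 642 without 51, 662 without 60, 766 without 74, 3260 without 82. Eye day 5 against day 3: 1204 without replicate 8, 1276 without 59, 1141 without 60, 3746 without 82. Race on any single day: 2165 without replicate 8, 1962 without 60. Eye day 7 against day 5: 74 without replicate 15, 76 without 16, 69 without 24, 627 without 37, 1892 without 38, 145 without 45, 612 without 46, 468 without 55, 130 without 67, 543 without 68, 655 without 82, 527 without 89, 416 without 90. Hindwing against forewing: 11 without replicate 21, 13 without 26, 11 without 31, 11 without 32, 13 without 69, 15 without 82, 11 without 89. Race in the hindwing: 1 without replicate 22. Race in the distal forewing: 1 without replicate 28. Distal against proximal forewing: 109 without replicate 55. Race by forewing section: 4 without replicate 76. Among the 56 values of named features, 2434 of 2654 kept their direction and side of the threshold, 189 lost the threshold, 29 gained it and 2 changed sign, both within the higher gain: HE669517 165670 to 170864 at -0.13 for race in the hindwing and HE671389 229316 to 229391 at 0.59 for race in the eye. Of 283 single-day race counts under alternatives, 100 lay within 1.5 times, 73 were higher and 110 lower. Signal over background was not analysed here, and dim arrays were told by median intensity alone. The self-test's 7% recovery of 2-fold changes, measured on simulated data, limits single-day race counts in the hindwing of day 3. Recovery in the real arrays may differ.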

Other observations

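All tests in this part except the splits of the samples were chosen after the results were seen; their bounds too were written after the counts of calls were known. The BD walk feature at 518010 to 518813 had race differences of opposite sign in the forewing sections, in the arrays that remained without the doubted ones. Its mean was lower in plesseni proximally and higher distally on all 4 days. Distally the log2 differences of days 1 and 3 were only 0.40 ± 0.70 and 0.19 ± 0.86 (SE). Probes that bind the alleles of the races unequally, but to the same degree in both sections, would cancel in the difference between sections, 2.72 ± 0.53 (SE). Unequal binding whose size varies with the section would not cancel. It cannot be told apart here, because the feature was picked for its difference and the distal difference alone did not pass (limma, adjusted p = 0.682). HE670865 438423 to 439107, a separate probe set, was also the most similar feature in the 40 hindwing and eye arrays alone (r = 0.920). In the forewing arrays, not used for that choice, its race difference differed between the sections by 4.54 standard errors. Whether the probe sets share probe or target sequence was not analysed here, so an error of the probes stays open. For the BD walk feature, leaving out any 1 of 44 forewing arrays left at least 4.60 standard errors, although the call was kept in 15 of 44. Chance stays open, since 17 of 100 splits gave at least 1 feature for this comparison (highest other 27), so that a race difference that depends on the wing section may be real here but remains a hypothesis.

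On single days the BD feature was 8.02-fold lower in plesseni in the proximal forewing of day 7 and 11.9-fold lower in the hindwing of day 7, with adjusted p of 0.204 and 0.0604 in limma, and 3.29-fold higher in the distal forewing of day 5 (adjusted p = 0.561). The similar feature was 5.45-fold and 7.13-fold lower at the former places (adjusted p = 0.353 and 0.11). None of these passed the threshold. In the eye of day 3 the log2 values of the BD feature were 11.16 on replicate 8 and 9.94 on replicate 60, both dim, and 5.86 on replicate 82.

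The race differences of day 1 could reflect plesseni sampled at a different point of development. Of 286 features called between races in the proximal forewing of day 1 without the doubted arrays, 168 moved in the direction of the step from day 1 to day 3 in the other wing sections, a share of 0.587. Among features called between day 3 and day 1 of the proximal forewing within 1 race, a known difference in stage, the share was 0.980 in malleti and 0.938 in plesseni. The lower share between races argues against a shift toward day 3 as the main source of these calls. A smaller shift mixed with race differences stays open, because the known difference was a full step. A shift to before day 1 was not tested. Of 331 called in the eye of day 1, the share that moved with the step in the wing was 0.502, but the known difference in stage gave only 0.801 and 0.573 there, so a shift in the eye stays open.

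Race differences correlated across features among the wing sections. With all arrays r was 0.371 between proximal and distal forewing, 0.473 between proximal forewing and hindwing and 0.482 between distal forewing and hindwing, against 0.0493, -0.291 and 0.0261 with the eye. Without the doubted arrays r was 0.461 between proximal and distal forewing, 0.442 between proximal forewing and hindwing and 0.484 between distal forewing and hindwing, against 0.191, 0.0706 and 0.171 with the eye, so that the value for distal forewing and eye changed sign. The r that chance groupings would give was not measured. Features are not independent replicates, and sections of 1 individual would share its deviations; whether replicates share individuals is not given in the sources used here.

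Splits of the samples were drawn 100 times per comparison, the real one included. For eye against wing, 1 split was as large, with 6139 features against at most 283; for distal against proximal forewing 1, with 67 against 1; for the wing steps 1 each, with 3805 against 832, 5270 against 1883 and 1679 against 487; and for the eye step from day 5 to day 7 also 1, with 276 against 265. The share of splits as large was under 0.05 for these, without adjustment over the comparisons. It was also under 0.05 for hindwing against forewing (3 splits, 7 features against 565), race in the proximal forewing (3 splits, 4 against 4) and race on any single day (3 splits, 4250 against 4320). In the latter comparisons other splits reached or passed the real count, so chance was not excluded there. For tissue and day comparisons redrawn groups mix tissues or days, which widens their spread and can lower the counts of such splits. The count for race on any single day leans on dim replicates 8 and 60 in the eye of day 3. Without the doubted arrays 2 splits were as large, with 1011 against 1012. The share was not under 0.05 for race in the eye (16 splits, 124 against 1665). Nor was it for the eye steps from day 1 to day 3 (26 splits, 1184 against 3343) and from day 3 to day 5 (10 splits, 1930 against 2862). Some splits gave several times the real count, as in race in the eye and hindwing against forewing, and the reason was not tested. Where the real count was 0, all 100 splits were as large: race in the distal forewing (highest other 10), race in the hindwing (92), race in all tissues (0), race by forewing section (1) and race by wing (2). Without the doubted arrays, the share was under 0.05 for race in the proximal forewing (2 splits, 28 against 45) and the distal forewing (3 splits, 15 against 18). Each still had another split above the real count. The share was not under 0.05 in the hindwing (11 splits, 3 against 40) or the eye (12 splits, 19 against 194).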
